A study of Homo sapiens with 16 samples.

How the data were processed

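Gene expression was measured by RNA sequencing of SmartSeq2 libraries, which are primed with oligo-dT, from 4 human immune cancer lines with and without 4 hours of stimulation. Per the labels the submitters aligned the reads with TopHat2 to the human build hg19; the program that counted reads, the gene annotation and the versions are not given in the sources used here. The 16 deposited files, 1 per library, hold values in TPM (transcripts per 1000000) from uniquely aligned reads, so a gene with a close copy elsewhere in the genome, such as CCL3 or CCL4, may be under-counted. The files list the same 27311 genes, and each library was checked to sum to 1000000. No scaling between libraries was visible in the values. Genes are identified by symbol, as the files give them, and no positions are reported.

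The values of a gene within a library are whole multiples of a step, the TPM of 1 read. Whole reads were recovered from these steps at a tolerance of 0.001 for 17860 of the 19092 genes above 0 in any library (93.5%). The other 1232 genes were above 0 in 1 library only. The recovered genes carried 99.994 to 99.997% of the TPM of a library. Their reads gave the depth, 4125221 to 8431295 reads per library: 7161600 and 8431295 in the THP-1 controls, 8353664 and 6634668 after LPS, 4125221 and 7333573 in the U937 controls, 6100202 and 7624966 after LPS, 8136821 and 6268801 in the Jurkat controls, 7437840 and 7286626 after stimulation, 6281897 and 6789239 in the BJAB controls, and 7853723 and 8170850 after stimulation. Tested on simulated data, the recovery was exact for 98.3% of genes and 3 of 18426 detected genes were not resolved. PCR reads are not independent molecules.

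Libraries were grouped by line and treatment into 8 groups of 2. Genes with a TPM of at least 1 in at least 2 libraries were tested (14398). limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) of all 16 libraries with 1 coefficient per group and a trend of the spread with level; the fit had 8 residual degrees of freedom and a prior of 3.18. The spread is thus pooled over the lines. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. On this scale the change of a gene with a low level is understated. Contrasts were stimulated against control in each line, the difference in LPS response between THP-1 and U937, and each untreated line against the mean of the other 3. In a stimulation, a gene with all libraries of a group at 0 is given by its values, without a fold change. A difference in LPS response for a gene with such a group depends on the pseudocount and is no bound. Replicate numbers are shared by the groups of a line, but no label says what they mark, so they were not used as a block in the reported fit.

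The rule for named genes, per stimulation, took the 8 largest rises and the 6 largest falls past the threshold with both stimulated libraries on the same side of both controls and a mean TPM of at least 5 in the higher group. It added up to 4 members past the threshold of each described list, or else the 2 with the highest TPM, the receptor genes of the ligand, and PPIF. For the LPS difference it took the 6 largest differences each way past the threshold with a mean TPM of at least 5 in at least 1 of the 4 groups, and 7 fixed inflammatory genes, and for the untreated lines the 5 lineage markers with the highest TPM. Small RNA genes were left out of these rankings. The lists, contrasts, threshold, rule and first set of alternatives were fixed before the data were examined.

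The 22 fixed lists cover NF-kB feedback and target genes, inflammatory cytokines, chemokines, interferon-stimulated genes, immediate-early and AP-1 genes, MAP kinase feedback genes, T cell activation, B cell activation and germinal centre genes, and components of the TLR4, T cell receptor, and B cell receptor and CD40 pathways. They also cover monocytic, T and B lineage markers, cell cycle, ribosome biogenesis, cholesterol synthesis, unfolded protein and stress response, inflammatory bowel disease associated, mitochondrially encoded and housekeeping genes. Some genes stand in more than 1 list and count in each. Lists with at least 5 tested members (21) were tested per stimulation with limma's camera at a preset correlation of 0.01, adjusted over all 84 tests, and again with an estimated correlation and with fry, which tests whether a list's genes move, on balance, one way. Members past the threshold were counted over all genes and adjusted over the list alone.

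The first set of alternatives was pseudocounts of 0.1 and 5, no filter on low values, a TPM minimum of 5, an added minimum change of 1 on the log2 scale, median-of-ratios scaling, quantile normalization, no trend, a replicate block, the libraries of the compared lines alone, the 8 controls alone, and each library left out in turn. After the data were seen, 4 alternatives were added: leaving out the first stimulated libraries of U937 and BJAB, voom on the recovered reads, removal of trends with GC content and transcript length in each library, and array weights. GC content came from GENCODE on GRCh38, matched by symbol for 24724 genes (90.5%). Relative transcript length came from the steps of the TPM values and correlated with the length in GENCODE at Spearman rho = 0.8. Both were known for 13861 of the tested genes. They were used for this correction and to describe the trends of each library with GC content and length. Levels of markers of other lineages in Jurkat and 4 gene families were also examined after the values were seen.

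The fit was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale per line. With the spread of each group as in the data, it recovered 16 to 31 of the first and 55 to 65 of the second. Of 14198 unchanged genes it called 3 in THP-1, 0 in Jurkat, 169 in U937 and 81 in BJAB (3.57, 0, 63.8 and 51.9% of the simulated calls), and 4 to 7 when all groups had equal spread. The simulated noise was independent between genes, without trends shared by the genes of a library. These shares therefore need not carry over to the real calls. Of 10 lists of 20 genes raised by 0.5, all 10 were called per line, and 0 of 10 unchanged lists. Members of these lists were simulated without correlation, so this test could not show false calls that arise where members move together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for loading, read recovery and figures.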

Results

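RNA was sequenced from 4 immune cancer lines, each untreated or exposed to an immune ligand for 4 hours, to measure which genes respond in each line. THP-1 and U937 are monocytic lines, Jurkat is a T cell line and BJAB is a B cell line. THP-1 cells carried dCas9-KRAB, a Cas9 without cutting activity joined to a repressor domain. They received bacterial lipopolysaccharide (LPS), the ligand of the receptor TLR4, at 1 µg/ml. U937 cells received LPS at 200 ng/ml. Jurkat cells received an antibody to CD3 at 5 µg/ml with the phorbol ester PMA at 100 ng/ml, and BJAB cells received antibodies to IgM at 10 µg/ml and to CD40 at 4 µg/ml. Each of the 8 groups held 2 libraries, and no label says whether these came from separate cultures. The p-values and standard errors below therefore rest on the spread between libraries of a group, which may be technical. This spread was pooled per gene over all 8 groups. The log2 difference between the 2 libraries had an SD of 0.96 in stimulated BJAB and 0.89 in U937 after LPS. It was 0.35 to 0.46 in the other 6 groups. For stimulated BJAB and U937 the standard errors may thus be too small.

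The deposited values are transcripts per 1000000 (TPM) for 27311 genes in 16 libraries. Whole reads recovered from the steps of the TPM values put the depth between 4125221 reads, in the first U937 control, and 8431295, in the second THP-1 control. Between 12731 and 15013 genes were above 0 in a library. Library pairs of 6 groups correlated at r = 0.984 to 0.991 over the tested genes. The LPS pair of U937 correlated at r = 0.943 and the stimulated pair of BJAB at r = 0.939. In the first LPS library of U937, the median log2 difference from the line's controls ran from 0.41 in the fifth of genes with the shortest transcripts to -1.13 in the fifth with the longest. In the first stimulated library of BJAB it ran from 0.21 in the fifth with the lowest GC content to -1.87 in the fifth with the highest. ACTB, which encodes the cytoskeletal protein beta-actin, was at 3779 and 8785 TPM in the LPS libraries of U937 and at 1858 and 7488 TPM in the stimulated libraries of BJAB. An alternative fit used below left out the first stimulated libraries of U937 and BJAB. The lone stimulated library of either line is then assumed to vary like the other groups. Its own spread is not seen, so calls of that fit in U937 and BJAB are no firmer than those with all libraries.

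**Figure D1:**
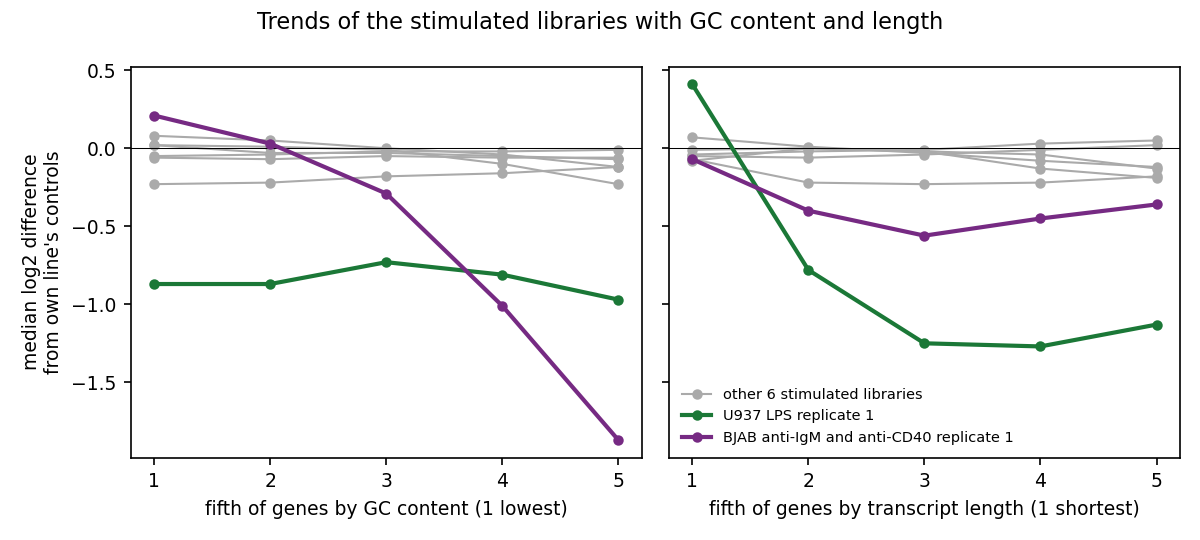
Median log2 difference in TPM between each stimulated library and the controls of its own line, over 5 equal groups of genes ordered by GC content and by transcript length. The first LPS library of U937 falls from 0.41 to -1.13 with length and the first stimulated library of BJAB from 0.21 to -1.87 with GC content, while the other 6 stimulated libraries (grey) stay nearer to 0.

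The untreated lines were compared first, to describe the cells before stimulation. In THP-1, 22 of 24 tested monocytic lineage markers were higher than the mean of the other 3 lines, led by the Fc receptor chain FCER1G at 3084 ± 54.6 TPM (SD, n = 2) and the granule proteases ELANE at 1604 ± 72.2 TPM and PRTN3 at 1514 ± 75 TPM. In U937, 17 of the 24 were higher and 4 lower, led by the granule protease CTSG at 4686 ± 42.7 TPM and ELANE at 2717 ± 166 TPM. In Jurkat, 22 of 23 T lineage markers were higher, among them the CD3 chain CD3D at 2216 ± 166 TPM (log2 difference 10.60, adjusted p = 2.67e-11) and the kinase LCK at 1224 ± 89.3 TPM. In BJAB, 20 of 23 B lineage markers were higher, with the antigen receptor chains CD79B at 3043 ± 54.9 TPM (log2 difference 10.31, adjusted p = 1.18e-08) and CD79A at 1622 ± 152 TPM. Markers of other lineages were mostly low: the median T lineage marker stood at 0.117 TPM in THP-1 and 0.124 TPM in BJAB, and the median B lineage marker at 0.207 TPM in Jurkat. Exceptions above the mean log2 level of the other 3 lines included the coreceptor CD4 in THP-1 (122.5 TPM) and U937 (112.6 TPM). CD4 is an exception only by its place on the T lineage list, since it was lower in Jurkat (19.35 TPM). Other exceptions were CTSG (487.3 TPM) and CD79A (148.2 TPM) in Jurkat, and LCK (61.88 TPM) and the surface receptor CD33 (82.06 TPM) in BJAB. Most of these stood below another line.

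Across all 14398 tested genes, limma called 5024 genes in THP-1 (2534 higher, 2490 lower), 5170 in U937 (2169 higher, 3001 lower), 5477 in Jurkat (3172 higher, 2305 lower) and 5681 in BJAB (2085 higher, 3596 lower) at an adjusted p under 0.05. The split depended on the scaling. Under median-of-ratios scaling it was 2928 higher and 2268 lower in THP-1, 2387 and 2940 in U937, 2634 and 2702 in Jurkat and 2213 and 3596 in BJAB. Under quantile normalization it was 2719 and 3295, 2693 and 2995, 2876 and 2939, and 2932 and 3267. The median log2 difference of all genes as deposited was -0.08, -0.11, 0.14 and -0.15 in these 4 comparisons. With only the 8 control libraries in the fit the counts were 8448, 8702, 8917 and 8945. Leaving out the first or the second THP-1 control gave 3242 and 3345 genes for THP-1, leaving out the first or the second U937 control gave 3278 and 3421 for U937, and leaving out the first Jurkat control gave 3633 for Jurkat.

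The genes that rose most after LPS in THP-1 included CXCL10, CCL4 and IL1B. The chemokine CXCL10, which attracts T cells, was listed at 0 TPM in both controls and at 30.3 and 24.3 TPM after LPS (adjusted p = 4.50e-05). CCL4, a chemokine for monocytes and lymphocytes, was also listed at 0 in both controls and at 16.1 and 17.2 TPM after LPS (adjusted p = 0.000576). The cytokine IL1B rose from 3.6 and 6.37 to 69.2 and 37.4 TPM, a log2 change of 3.16 ± 0.37 (SE, n = 2 per group; adjusted p = 0.00443). IGFBP3, a binding protein of insulin-like growth factors, rose by 2.98 ± 0.17 (adjusted p = 1.92e-05), and the hyaluronan-binding protein TNFAIP6 by 2.93 ± 0.31 (adjusted p = 0.00205). TIFAB (1.64 ± 0.26) and the transcription factor MSC (1.57 ± 0.17) rose as well. No fall met that rule, although 7 genes with lower levels passed the threshold.

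Of the fixed gene lists, chemokines (2 of 16 rose), inflammatory cytokines (1 of 15 rose) and B cell activation genes (1 of 25 rose) held genes past the threshold in THP-1. NF-kB feedback and target genes were shifted upward as a group, with a median log2 change of 0.84, although 0 of 23 passed over all genes. Over all genes 2 of them rose under median-of-ratios scaling, 4 under quantile normalization and 7 with the first stimulated libraries of U937 and BJAB left out. Chemokines that rose numbered 2, 4 and 3 in these fits, cytokines 1, 2 and 2, and B cell activation genes 3, 4 and 3. Adjusted over the list alone, 12 of the 23 passed, all higher. NFKBIA, the inhibitor of NF-kB that is itself an NF-kB target, was at 85.5 and 77.3 TPM in controls and 213 and 187 TPM after LPS (adjusted p = 0.132). It passed with those libraries left out (adjusted p = 0.00351) and in 3 of its 17 alternatives in all. In the camera test the NF-kB list (adjusted p = 4.68e-24) and the chemokines (1.49e-19) were called upward, and both calls held with an estimated correlation (adjusted p = 0.00786 and 0.00479). Interferon-stimulated genes (5.29e-08), B cell activation genes (8.77e-10), cytokines (4.01e-05), MAP kinase feedback genes (9.87e-05) and immediate-early genes (0.00148) were called upward too. Those 5 calls were lost with an estimated correlation (adjusted p = 0.0931, 0.0544, 0.149, 0.242 and 0.25 in that order). Adjusted over each list alone, 8 chemokines rose, 4 cytokines rose and 1 fell, 7 B cell activation genes rose, and 0 members of the other 3 lists passed.

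The receptor genes TLR4 (8.50 and 9.28 TPM in controls, 5.98 and 6.99 TPM after LPS), LY96 (2.92 and 0.419, then 0.426 and 1.96 TPM) and CD14 (6.31 and 5.43, then 4.49 and 8.68 TPM) did not pass in THP-1. PPIF, which encodes the mitochondrial protein cyclophilin D, was at 442 and 486 TPM in controls and 502 and 445 TPM after LPS (log2 change 0.03 ± 0.35). limma called 24 genes in THP-1, 17 higher and 7 lower, and 522 had an unadjusted p under 0.05. The count was 14 without the first control, 70 (22 higher, 48 lower) without the first LPS library, 37 with the first stimulated libraries of U937 and BJAB left out, 8 by voom on the recovered reads and 0 in a limma fit of the 4 THP-1 libraries alone (1027 with an unadjusted p under 0.05). TIFAB missed the threshold with those 2 libraries left out (adjusted p = 0.0562; range over all its alternatives 0.000312 to 1).

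LPS in U937 raised CXCL10 from 0 and 1.48 to 46.1 and 44.3 TPM, a log2 change of 4.87 ± 0.32 (SE, n = 2 per group; adjusted p = 5.95e-05). CCL4 was listed at 0 TPM in both controls and at 53.2 and 25.3 TPM after LPS (adjusted p = 6.43e-05). TNFAIP6 was listed at 0 in both controls and at 4.56 and 5.74 TPM after LPS (adjusted p = 0.0117). The 1 lower gene, the microRNA gene MIR221, went from 4.86 and 5.46 TPM to a listed value of 0 in both LPS libraries. It lies outside the rule for named genes and was chosen after its values were seen. In so short a gene a few reads make several TPM, so this call may rest on few reads. NFKBIA was at 57.3 and 65.6 TPM in controls and 175 and 174 TPM after LPS (log2 change 1.49 ± 0.26, adjusted p = 0.124). It passed with the first stimulated libraries of U937 and BJAB left out (adjusted p = 0.0113) and in 4 of its 17 alternatives in all. The chemokine CCL2 was at 275 and 314 TPM in controls and 1182 and 565 TPM after LPS (adjusted p = 0.329). TLR4 was at 30.6 and 26.9 TPM in controls and 6.23 and 19.5 TPM after LPS (adjusted p = 0.329), LY96 at 14.8 and 10.8, then 18.9 and 11 TPM, and CD14 was listed at 0 in all 4 libraries. PPIF was at 599 and 568 TPM in controls and 231 and 567 TPM after LPS (adjusted p = 0.339).

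Chemokines were the list with the clearest shift in U937, with a median log2 change of 1.20. Of 16 tested members, 2 rose over all genes and 9 rose when adjusted over the list alone (camera adjusted p = 1.31e-17, and adjusted p = 0.00479 with an estimated correlation). NF-kB feedback and target genes (5.48e-06; 0 of 23 passed, 2 over the list alone), B cell activation genes (0.00573; 1 of 25 rose, 2 over the list alone) and cytokines (0.0403; 0 of 15 passed, 0 over the list alone) were called upward as well. Those 3 calls were lost with an estimated correlation (adjusted p = 0.141, 0.424 and 0.534). The median change of the last pair of lists was 0 while their means were 0.19 and 0.11, and the cytokine call was also lost under median-of-ratios scaling (adjusted p = 0.0963). These shifts stand against a median of -0.25 over all genes in this comparison, which median-of-ratios scaling brought to 0.

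In U937, limma called 4 genes, 3 higher and 1 lower, and 2176 had an unadjusted p under 0.05. The count was 5001 (734 higher, 4267 lower) without the second LPS library, when the first LPS library stands alone and is assumed to vary like the other groups, 8 without the second control, 13 under median-of-ratios scaling, 14 under quantile normalization, and 0 in a limma fit of the 4 U937 libraries alone (458 with an unadjusted p under 0.05). In data simulated with the spread of each group, 169 of 14198 unchanged genes were called in U937, 63.8% of the simulated calls, and TNFAIP6 missed the threshold with the first LPS library left out beside that of BJAB (adjusted p = 0.0793; range over its alternatives 0.00131 to 0.631).

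The responses of both monocytic lines to LPS were compared by a test of the difference itself. IGFBP3 rose in THP-1 and was listed at 0 in all 4 U937 libraries, a difference in response of 2.98 ± 0.23 on the log2 scale (SE, n = 2 per group; adjusted p = 0.000391). With U937 at 0 this value is the change in THP-1 alone and depends on the pseudocount. The difference, THP-1 minus U937, was positive for 5 and negative for 2 of the 7 genes that passed. The other 6 were chosen after their values were seen, and each had a group at 0. MIR221 was at 0 in all 4 THP-1 libraries and went to 0 in U937, and the small RNA gene SNORD124 went from 2.91 and 2.50 TPM to 0 in THP-1 and was at 0 in U937. Both genes are so short that a few reads make several TPM, so their calls may rest on few reads. FEV (0.479 and 0.686, then 2.65 and 3.21 TPM) and CPZ (0.944 and 1.01, then 3.92 and 4.27 TPM) were higher after LPS in THP-1 and at 0 in U937. TEX41 was at 0 and 0.269, then 1.80 and 1.64 TPM in THP-1 and at 0.112 and 0.0628, then 0 TPM in U937. LINC00379 was at 1.06 and 0.909, then 0.462 and 0 TPM in THP-1 and at 0, then 0.955 and 1.49 TPM in U937. The 7 inflammatory genes fixed for this test did not pass. IL1B went from 2.85 and 5.82 to 10.3 and 9.22 TPM in U937, and its response differed from that in THP-1 by 2.09 ± 0.53 (adjusted p = 0.408). The differences for CXCL8, TNFAIP3, TNF and IFIT1 were 1.49, 1.31, 1.13 and 0.36, and that for NFKBIA was -0.21. With the first stimulated libraries of U937 and BJAB left out, the same 5 differences were 0.02, 0.37, 0.78, 0.12 and -0.21, and that for IL1B was 2.16.

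Over the 14398 tested genes the log2 changes of both lines correlated at Pearson r = 0.104 and Spearman rho = 0.107. Leaving out each library of these lines in turn gave r from 0.02 (rho = -0.029, without the second THP-1 LPS library) to 0.152 (without the first THP-1 control). It gave 0.027 (rho = -0.009) without the first U937 LPS library and 0.035 without the second THP-1 control. This is a correlation across genes, which are not independent replicates. Over the 25 genes called in either line r was 0.671 and rho 0.586.

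The lines also differ in LPS dose and in dCas9-KRAB, so the difference cannot be assigned to the line alone, and LINC00379, FEV, CPZ and TEX41 missed the threshold with the first stimulated libraries of U937 and BJAB left out (adjusted p = 0.0814, 0.185, 0.185 and 0.185). The count of 7 became 2567 without the second LPS library of U937, 17 without either LPS library of THP-1, 3 without the first THP-1 control or the first U937 LPS library, and 0 by voom on the recovered reads (770 with an unadjusted p under 0.05).

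The genes that rose most after anti-CD3 and PMA in Jurkat included ATP6V0A4, GZMB, PLAU and BCL2A1. ATP6V0A4, a subunit of the vacuolar proton pump, was listed at 0 TPM in both controls and at 170 and 179 TPM after stimulation (adjusted p = 6.95e-11). The cytotoxic granule protease GZMB rose from 2.27 and 1.41 to 329 and 364 TPM, a log2 change of 6.95 ± 0.28 (SE, n = 2 per group; adjusted p = 7.29e-08). The plasminogen activator PLAU rose by 6.96 ± 0.71 and the survival gene BCL2A1 by 6.73 ± 0.30. The cell cycle inhibitor CDKN1A rose by 6.17 ± 0.74, the non-coding RNA LINC00659 by 5.91 ± 0.57, the transcription factor EGR1 by 5.89 ± 0.30 and the MAP kinase phosphatase DUSP5 by 5.82 ± 0.36. The largest falls included RAG1 and RAG2, which recombine antigen receptor genes in early lymphocytes. RAG1 fell from 17.6 and 16.3 to 0.637 and 0.182 TPM (log2 change -3.69 ± 0.17, adjusted p = 1.70e-07). RAG2 changed by -3.64 ± 0.17 and the surrogate light chain VPREB1 by -3.85 ± 0.54. LINC01225 (-3.16 ± 0.38) and the transcriptional regulator LMO1 (-2.96 ± 0.23) fell too, and LINC01882 went from 9.70 and 8.47 TPM to a listed value of 0.

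T cell activation genes rose together in Jurkat, with 14 of 20 tested members higher and 1 lower. The interleukin 2 receptor chain IL2RA rose from 1.04 and 0 to 54.6 and 57.4 TPM (5.32 ± 0.26), the early activation antigen CD69 from 50.3 and 37.5 to 627 and 815 TPM (4.01 ± 0.27), and the inhibitory receptor PDCD1 by 3.94 ± 0.19. Of the immediate-early and AP-1 genes 11 of 18 rose, among them NR4A1 (5.46 ± 0.56), EGR2 (4.64 ± 0.34) and FOS (3.51 ± 0.53). Of the MAP kinase feedback genes 11 of 18 rose, including PHLDA1 (5.79 ± 0.25), DUSP6 (5.36 ± 0.51) and DUSP2, which went from 40.8 and 78.1 to 1516 and 2179 TPM. Of the NF-kB genes 11 of 23 rose, with IER3 (4.88 ± 0.25), TRAF1 (4.75 ± 0.38) and RELB (4.57 ± 0.68) next to BCL2A1. Of the B cell activation genes, many of which T cells also induce, 13 of 25 rose. Adjusted over each list alone, 14 T cell activation genes rose and 1 fell, 12 immediate-early genes rose and 1 fell, 13 MAP kinase feedback and 14 NF-kB genes rose, and 14 B cell activation genes rose and 1 fell. All 5 lists were called upward by camera (adjusted p = 6.68e-26, 1.43e-17, 1.34e-19, 2.37e-16 and 5.20e-14 in the order given), and the calls held with an estimated correlation (adjusted p = 0.00154, 0.0107, 0.0165, 0.0172 and 0.0235).

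Of 16 chemokines 6 rose, among them CXCL3 (3.72 ± 0.27) and CCL1 (2.74 ± 0.29), while CCL4 and the neutrophil attractant CXCL8 were listed at 0 in both controls and reached 17.5 and 8.08 TPM and 10.0 and 10.0 TPM. Of 15 cytokines 5 rose, including the lymphotoxin chain LTB (4.59 ± 0.25), IL23A (3.83 ± 0.78) and LTA (1.70 ± 0.28), and CSF2, listed at 0 in both controls, reached 5.72 and 11.8 TPM. The chemokine call (camera adjusted p = 5.38e-07) held with an estimated correlation (adjusted p = 0.0372), and the cytokine call (1.75e-06) did not (adjusted p = 0.108). By fry both lists were called (adjusted p = 0.000487 and 0.000774). Over each list alone 7 chemokines and 7 cytokines rose. Interferon-stimulated genes were called downward (adjusted p = 0.0403, but adjusted p = 0.551 with an estimated correlation): 4 of 43 fell, among them the antiviral genes RSAD2 (-1.87 ± 0.44), DHX58 (-1.29 ± 0.22) and XAF1 (-1.15 ± 0.27), and the death ligand TNFSF10 rose by 3.09 ± 0.29. Over the list alone 6 fell and 1 rose. Of the unfolded protein and stress response genes 3 of 24 rose (4 over the list alone): CDKN1A, the stress-induced transcription factor DDIT3 (2.45 ± 0.37) and the chaperone HSP90B1 (1.38 ± 0.14). Of the genes associated with inflammatory bowel disease 6 of 38 rose (6 over the list alone), including IL2RA, the receptor GPR65 (2.43 ± 0.24) and the transporter SLC22A4 (1.93 ± 0.42), while ICOSLG, listed at 0 in both controls, reached 2.74 and 3.71 TPM. Both of these lists were called upward (adjusted p = 0.00104 each), and neither call held with an estimated correlation (adjusted p = 0.434 and 0.689). In Jurkat 12 stress response genes rose and 4 fell, 13 inflammatory bowel disease genes rose and 1 fell, and 4 interferon-stimulated genes rose and 8 fell with the first stimulated libraries of U937 and BJAB left out.

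Genes that define the T lineage moved in both directions in Jurkat: 7 of 23 rose and 4 fell (7 and 10 over the list alone). The signalling adaptor LAT rose from 290 and 274 to 1451 and 1595 TPM (2.43 ± 0.29, adjusted p = 0.000315) and the surface receptor CD6 by 1.88 ± 0.19, while RAG1 and the signalling adaptor SH2D1A (-1.84 ± 0.18) fell. Among T cell receptor pathway components 5 of 20 rose and 2 fell (6 and 3 over the list alone), with LAT among the rises and RASGRP1 (-2.39 ± 0.22) and GRAP2 (-1.56 ± 0.32) as the falls. Neither list was called by camera (adjusted p = 0.672 and 0.131), while fry called the T lineage markers downward (adjusted p = 0.0207). The CD3 chains CD3E (371 and 393 TPM in controls, 354 and 244 TPM after stimulation) and CD247 (251 and 277, then 268 and 247 TPM) did not pass. PPIF was at 197 and 201 TPM in controls and 339 and 290 TPM after stimulation (log2 change 0.65 ± 0.35, adjusted p = 0.515); it passed with the first stimulated libraries of U937 and BJAB left out (adjusted p = 0.0199; range over its alternatives 0.0199 to 0.915). Single members of other lists passed too: BACH2 rose (2.75 ± 0.17) and P2RY8 (-2.36 ± 0.58) and GCSAM (-0.82 ± 0.19) fell among germinal centre genes, the scavenger receptor CD68 rose (3.03 ± 0.54) and CEBPE (-1.81 ± 0.37) fell among monocytic markers, the coactivator POU2AF1 rose (2.71 ± 0.39) among B lineage markers, and the signalling adaptor BCL10 rose (1.01 ± 0.25) among B cell receptor and CD40 pathway components; of the 17 alternatives, the call held in 8 for GCSAM, 9 for BCL10, 10 for CEBPE and 11 for P2RY8.

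In total limma called 701 genes in Jurkat, 435 higher and 266 lower, and 586 of them changed by at least 1 on the log2 scale. The log2 changes in Jurkat do not use libraries of other lines, so leaving those out changes only the pooled spread. The count was 1942 (966 higher, 976 lower, all 701 among them) with the first stimulated libraries of U937 and BJAB left out, 431 and 448 without the first or the second Jurkat control, 461 without the second stimulated library, and 368 in a limma fit of the 4 Jurkat libraries alone.

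**Figure D2:**
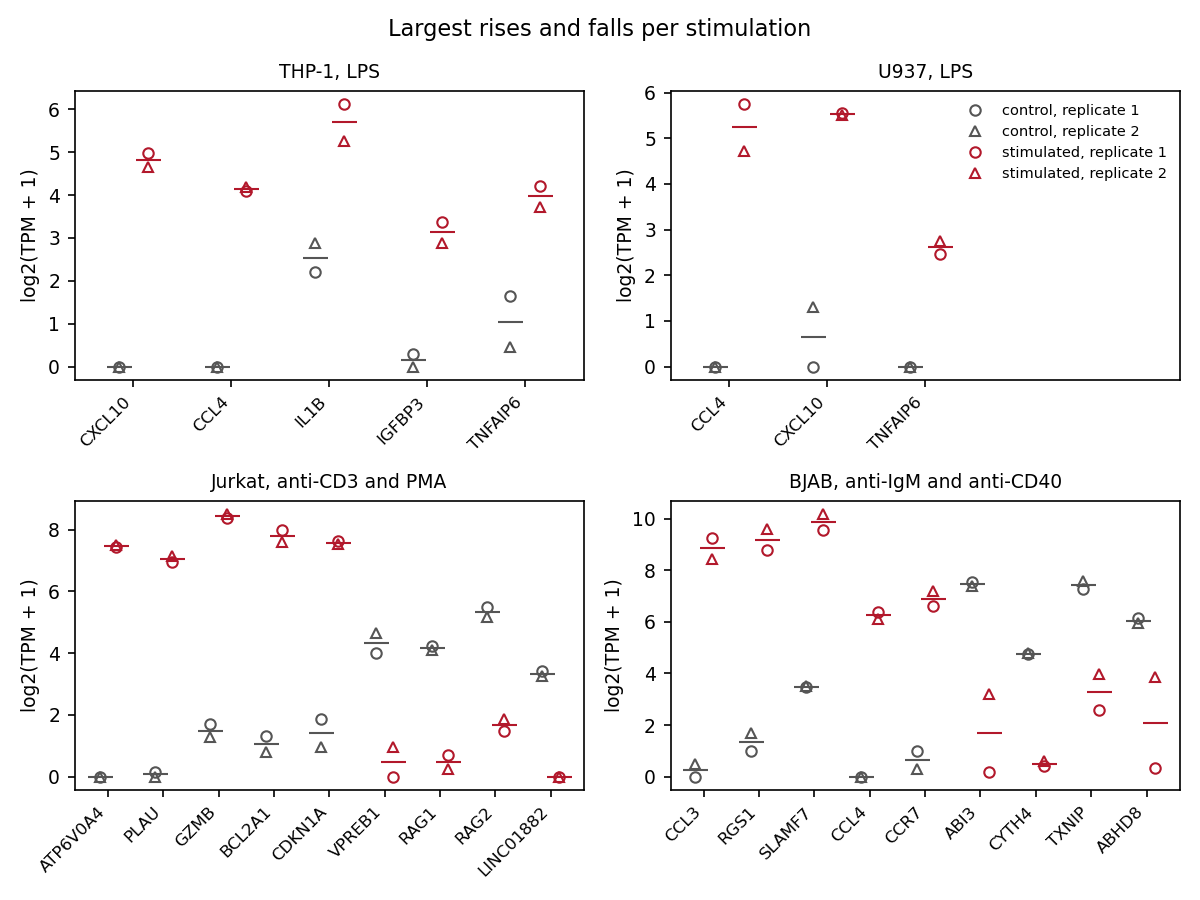
Log2(TPM + 1) of the largest rises and falls named by the rule in each stimulation, with controls in grey and stimulated libraries in red, circles for replicate 1, triangles for replicate 2 and a dash at each mean. GZMB in Jurkat goes from 2.27 and 1.41 to 329 and 364 TPM, and the stimulated BJAB libraries differ most from each other for ABI3 (0.122 and 8.31 TPM) and ABHD8 (0.245 and 13.5 TPM).

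The genes that rose most after anti-IgM and anti-CD40 in BJAB included CCL3, RGS1, SLAMF7 and CCR7. The chemokine CCL3 rose from 0 and 0.395 to 615 and 350 TPM, a log2 change of 8.62 ± 0.52 (SE, n = 2 per group; adjusted p = 3.01e-06). CCL4 was listed at 0 in both controls and reached 83 and 68.3 TPM. RGS1, a regulator of G protein signalling, rose by 7.86 ± 0.30 (adjusted p = 3.56e-07) and its relative RGS2 went from 61.3 and 62.8 to 2315 and 3677 TPM (5.53 ± 0.47). The receptors SLAMF7 (6.40 ± 0.35) and LY9 (5.38 ± 0.34) of the SLAM family, the lymph node homing receptor CCR7 (6.25 ± 0.31) and the stress-induced factor GDF15 (4.91 ± 0.50) rose as well. The largest falls were ABI3 (-5.78 ± 0.81), CYTH4 (-4.28 ± 0.40), the thioredoxin inhibitor TXNIP (-4.16 ± 0.60), ABHD8 (-3.96 ± 0.81), the receptor of platelet-activating factor PTAFR (-3.89 ± 0.35) and the signalling adaptor SLA (-3.78 ± 0.29). With the first stimulated libraries of U937 and BJAB left out, GDF15 changed by 5.95, and ABI3, ABHD8, TXNIP and PTAFR by -4.26, -2.19, -3.47 and -3.25.

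Of the MAP kinase feedback genes 7 of 18 rose in BJAB, including RGS1, RGS2, DUSP10 (2.69 ± 0.51) and DUSP5 (2.05 ± 0.36). Of the immediate-early genes 4 of 18 rose and 1 fell, with EGR1 going from 10 and 14 to 310 and 296 TPM (4.56 ± 0.30, adjusted p = 4.47e-06), ATF3 (3.71 ± 0.33) and KLF6 (3.11 ± 0.24) up and FOSB (-1.14 ± 0.27) down. B cell activation genes (6 of 25 rose, 1 fell) included CCL3, CCL4, CCR7 and CD69 (3.77 ± 0.27), and NF-kB genes (6 of 23 rose, 3 fell) included BIRC3 (3.73 ± 0.47), BCL2A1 (3.32 ± 0.30) and CD83 (2.12 ± 0.44) among the rises and NINJ1 (-2.22 ± 0.58) among the falls. Of 16 chemokines 2 rose, and of 20 cholesterol synthesis genes 2 rose, MSMO1 (1.87 ± 0.47) and CYP51A1 (1.59 ± 0.31). The count of cholesterol synthesis genes that rose was 8 under median-of-ratios scaling, 6 under quantile normalization and 9 with the first stimulated libraries of U937 and BJAB left out. In that last fit BIRC3 changed by 2.74, NINJ1 by -0.95 and FOSB by -0.67. All 6 lists were called upward by camera (adjusted p = 1.04e-07, 1.06e-05, 0.000169, 0.00238, 0.00214 and 0.00081 in that order), and all 6 calls were lost with an estimated correlation (adjusted p = 0.117, 0.117, 0.216, 0.362, 0.17 and 0.534). By fry, the adjusted p of the 6 lists was 0.00276, 0.0051, 0.0051, 0.188, 0.00478 and 0.561 in the same order. The NF-kB and cholesterol synthesis lists were thus not called by fry either. Over the lists alone, 8 MAP kinase feedback genes rose and 1 fell, 5 immediate-early genes rose and 2 fell, 6 B cell activation genes rose and 2 fell, 6 NF-kB genes rose and 3 fell, 2 chemokines rose and 4 cholesterol synthesis genes rose. The median change of the NF-kB list and of the chemokines was 0, with means of 0.43 and 0.99.

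Of 43 interferon-stimulated genes 11 fell in BJAB, 0 rose and 32 did not pass (17 fell over the list alone). The falls included the interferon response regulator USP18 (-2.32 ± 0.27, adjusted p = 0.000397), IRF9 (-2.24 ± 0.42), OASL (-2.24 ± 0.32) and IFIT2 (-2.12 ± 0.42). Under median-of-ratios scaling 8 fell and 0 rose, and under quantile normalization 6 fell and 0 rose. It was 17 and 0 with the first stimulated libraries of U937 and BJAB left out, where IFIT2 changed by -2.76. The list was called downward by camera (adjusted p = 8.88e-05, but adjusted p = 0.208 with an estimated correlation) and by fry (adjusted p = 0.00175). Of 23 B lineage markers 8 fell and 2 rose (10 and 2 over the list alone), and 9 fell and 2 rose under either scaling. The transcription factor SPIB (-2.63 ± 0.53), POU2AF1 (-2.35 ± 0.39) and the antigen receptor chain CD79B (3005 and 3082 TPM in controls, 321 and 1106 TPM after stimulation; -2.35 ± 0.57) fell. The antigen loading gene HLA-DMB rose from 2.05 and 1.80 to 29.6 and 30.6 TPM (3.41 ± 0.15, adjusted p = 6.15e-07), and MS4A1, which encodes CD20, rose by 1.01 ± 0.18. The list was called downward (adjusted p = 0.0104); the call was lost with an estimated correlation (adjusted p = 0.624), as was that of CD79B with the first stimulated libraries of U937 and BJAB left out (adjusted p = 0.0738; range over its alternatives 0.00174 to 0.434). In the same fit CD79B, SPIB and POU2AF1 changed by -1.46, -1.67 and -1.56. CD79A, at 1514 and 1729 TPM in controls and 284 and 1305 TPM after stimulation, and CD40, at 39.2 and 43.2, then 38.0 and 71.2 TPM, did not pass. PPIF was at 198 and 279 TPM in controls and 185 and 255 TPM after stimulation (adjusted p = 0.971).

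Other lists held calls in BJAB without being called as a whole by camera. Germinal centre genes (6 of 16 fell, 2 rose; 10 and 2 over the list alone; adjusted p = 0.0757) included P2RY8 (-2.30 ± 0.58) and GCSAM (-1.78 ± 0.19) below, and BACH2 (2.07 ± 0.17) and RGS13 (1.93 ± 0.31) above, the controls. Among cytokines (2 of 15 rose, 1 fell; adjusted p = 0.227) the anti-inflammatory cytokine IL10 rose from 29.6 and 24.5 to 476 and 562 TPM (4.21 ± 0.30, adjusted p = 1.04e-05), IL1RN rose by 1.34 ± 0.25 and IL18 changed by -1.06 ± 0.23. Of the stress response genes 3 of 24 rose and 3 fell (adjusted p = 0.103): ATF3 and DDIT3 (3.22 ± 0.37) rose, and DDIT4 (-3.26 ± 0.70) and the chaperone HSPA1B (-3.00 ± 0.66) fell. T cell activation genes (2 of 20 rose, 1 fell; adjusted p = 0.0993) held CD69, CD83 and TNFRSF18 (-2.86 ± 0.68). Of the inflammatory bowel disease genes 2 of 38 rose and 1 fell (adjusted p = 0.285), with IL10 and the plasma cell regulator PRDM1 (2.19 ± 0.32) up and ORMDL3 (-1.26 ± 0.31) down. TLR4 (-2.07 ± 0.37), the myeloid and B cell transcription factor SPI1 (-2.96 ± 0.55) and CD247 (-1.62 ± 0.21) fell, PTCRA went from 0.584 and 2.15 TPM to a listed value of 0, and the ribosome biogenesis gene WDR43 rose by 0.85 ± 0.20. P2RY8, DDIT4, HSPA1B, TNFRSF18 and SPI1 changed by -1.54, -1.79, -1.90, -1.40 and -1.96 with the first stimulated libraries of U937 and BJAB left out. In that fit 10 stress response genes rose and 6 fell, and 5 inflammatory bowel disease genes rose and 6 fell.

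limma called 921 genes in BJAB, 235 higher and 686 lower, so that 25.5% of the calls were higher. The share was 39.7% under median-of-ratios scaling and 51.0% under quantile normalization, and the median log2 change of all genes was -0.14 as deposited. Of the 12 calls in a limma fit of the 4 BJAB libraries alone, 11 were higher and 1 lower. The excess of falls was thus not seen without the spread pooled over the lines, in a fit with few calls. The count was 408 and 320 without the first or the second control, 447 (171 higher, 276 lower) without the first stimulated library, 4179 (928 higher, 3251 lower) without the second, when the first stands alone and is assumed to vary like the other groups, 214 with array weights and 12 in a limma fit of the 4 BJAB libraries alone. In data simulated with the spread of each group, 81 of 14198 unchanged genes were called in BJAB, 51.9% of the simulated calls, and the calls of CD79B, NINJ1, FOSB, IL18, ORMDL3, P2RY8, MSMO1 and PTCRA held in 9 or fewer of their alternatives.

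**Figure D3:**
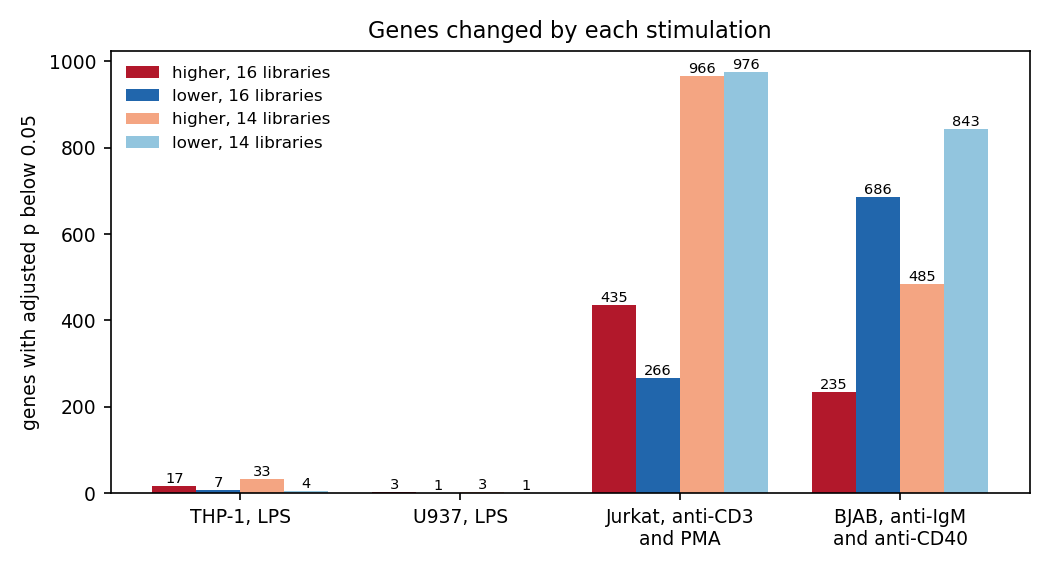
Number of genes called higher and lower by limma at an adjusted p under 0.05 in each stimulation, with all 16 libraries and with the first stimulated libraries of U937 and BJAB left out. With all libraries the bars stand at 17 and 7 genes in THP-1, 3 and 1 in U937, 435 and 266 in Jurkat and 235 and 686 in BJAB.

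CCL4 was higher in all 4 stimulations. THP-1 and U937 shared 3 higher genes, CCL4, CXCL10 and TNFAIP6. Jurkat and BJAB shared 35 higher genes, where independent lists of these sizes would share 7.1. These included the transcription factors EGR1, NR4A3, KLF6, KLF10 and NFKB1, the feedback inhibitors NFKBIA, DUSP5, DUSP10 and PHLDA1, and the surface molecules CD69, CD83, CCR7 and SLAMF7. They also shared 23 lower genes (12.67 for independent lists), among them P2RY8, GCSAM, DHX58, BCL11A and SREBF1. The numbers for independent lists count all tested genes, whichever line expresses them, and both lists were tested with the same pooled spread. Part of either excess may come from this. In total 38 genes were higher and 24 lower in at least 2 stimulations. The sum of 62 became 265 with the first stimulated libraries of U937 and BJAB left out, and genes named here beyond the rule were chosen after the overlap was seen.

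The list of 26 cell cycle genes was not called in the 4 stimulations, with camera adjusted p of 0.276 in THP-1, 0.774 in U937, 0.196 in Jurkat and 0.635 in BJAB. Ribosome biogenesis genes (0.0553, 0.692, 0.3 and 0.415 in the same order of lines), TLR4 pathway components (0.825, 0.347, 0.475 and 0.887) and T cell receptor pathway components (0.303, 0.987, 0.131 and 0.965) were not called. Neither were B cell receptor and CD40 pathway components (0.0679, 0.872, 0.772 and 0.872), monocytic lineage markers (0.887, 0.415, 0.981 and 0.352), T lineage markers (0.514, 0.596, 0.672 and 0.965) and housekeeping genes (0.965, 0.965, 0.881 and 0.718). With the first stimulated libraries of U937 and BJAB left out, cell cycle genes were called downward in THP-1 (adjusted p = 0.000141) and Jurkat (0.00119), cholesterol synthesis genes downward in THP-1 (0.00107) and Jurkat (0.000606), and ribosome biogenesis genes downward in THP-1 (0.000476) and upward in BJAB (0.000898). In that fit B cell receptor and CD40 pathway components (0.0252), T cell activation genes (0.0359) and inflammatory bowel disease genes (0.0135) were called upward in THP-1, and the last list also in U937 (0.00481). In the same fit, germinal centre genes were called downward (0.00481) and stress response genes upward (0.00168) in BJAB, and B lineage markers lost their call there (0.068). None of the 9 mitochondrially encoded genes sought was listed under its symbol, so that list was not tested. Of the 84 tests on 21 lists, 29 were called, 26 upward and 3 downward, and 9 with an estimated correlation. In 4 of the called and 28 of the other tests the median or the mean of the list was 0 or differed in sign from the test.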

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

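The tests of the libraries that stand apart and the removal of GC and length trends were chosen after these results had been seen. The test of the difference in LPS response, leaving out each library in turn, median-of-ratios scaling and quantile normalization were planned, but their use as tests of the split in BJAB was chosen afterwards.

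The responses to LPS differed between THP-1 and U937 for 7 genes by limma's test of the difference. Each of the 7 had a group at 0, and the calls of the short genes MIR221 and SNORD124 may rest on few reads. The largest such difference was that of IGFBP3, at 2.98 ± 0.23 on the log2 scale (adjusted p = 0.000391): it was at 0.228 and 0 TPM in THP-1 controls and 9.35 and 6.42 TPM after LPS, and at 0 in all 4 U937 libraries. With U937 at 0 this difference is the change in THP-1 alone and depends on the pseudocount. The count was 2567 without the second LPS library of U937, 17 without either LPS library of THP-1, and 3 without the first THP-1 control or the first U937 LPS library. The lone library of a group is then assumed to vary like the other groups.

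The first LPS library of U937 and the first stimulated library of BJAB stood apart from their partners, at r = 0.943 and 0.939 against 0.984 to 0.991 in the other 6 pairs. Lower depth is argued against, since the shallowest library, the first U937 control, correlated with its partner at r = 0.99 and the libraries in question held 6100202 and 7853723 reads. Both carry trends, with transcript length in U937 (rho = -0.43) and with GC content in BJAB (rho = -0.55). Their partners leaned the same way (rho = -0.25 and -0.21). The Jurkat controls, each set against the other, had a rho of -0.4 and 0.4 with GC content at r = 0.99. A rho of this size alone thus does not set a library apart. Their removal raised the correlations to 0.952 and 0.961, still below 0.985, the lowest of the other 6 pairs after the same removal. The removal was fitted to genes of higher level and made smaller for genes near 0. How much of the trends it left in these libraries was not measured. The trends as removed thus account for part of the gap, and whether they are the whole cause cannot be told. No biological explanation was tested, since both libraries share their group with their partner, and a trend of another kind or a difference in the cells may remain.

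Lower calls outnumbered higher calls in stimulated BJAB (686 against 235, 25.5% higher, and 22.2 to 38.3% with each BJAB library left out in turn). Genes move together within these libraries, so the spread of the share is read from left-out libraries. Without the first stimulated library 38.3% of the calls were higher, 43.7% under median-of-ratios scaling and 50.5% under quantile normalization. These shares rest on 1 stimulated library, whose own spread is not seen, so that library alone cannot be told apart from a true excess of falls. Removal of the GC and length trends gave 37.3%, and 36.8 to 44.1% with each library left out. This range of 7.3 is wider than the gap between 44.1% and an even split, so these trends stay open as well. The scale of the libraries cannot be told apart either: median-of-ratios scaling gave 39.7% (38.6 to 43.7% over left-out libraries) and quantile normalization 51.0% (49.1 to 55.6%), and no value here says which scale is right. An effect of the stimulation on the balance of rises and falls stays open and untested.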

How the results depend on the processing

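Leaving out 2 libraries, voom, the GC and length correction and array weights were chosen after seeing the data; the other alternatives were planned. Of the named genes' results, 3479 were on the same side of the threshold in the same direction, 312 lost their call, 39 gained one, 109 uncalled values changed sign or moved, and 0 reversed. For single lists these numbers were 475, 40, 28, 44 and 1. That one was the inflammatory bowel disease list in U937, uncalled and downward as reported (adjusted p = 0.669) and called upward with 2 libraries left out (adjusted p = 0.00481). For counts, 118 stayed within 1.5 times the reported value and 70 did not. A count that stays can still hold other genes. Of the 24 genes in THP-1, 10 were kept among 19 with a pseudocount of 0.1. Quantile normalization kept 18 among 34 and median-of-ratios scaling 22 among 29. Of the 921 in BJAB, quantile normalization kept 606 among 1010. For the correlation of LPS responses (r = 0.104), 12 moved by at most 0.1, some of them toward 0 by over 1.5 times (0.048 with a pseudocount of 0.1, 0.027 with 2 libraries left out, 0.02 to 0.152 with each library left out), and 1 moved further. The 70 and this 1 follow, and the cause was not tested unless stated. Where libraries of other lines are left out, the log2 changes in THP-1 and Jurkat stay as reported. Only the spread pooled over the lines differs there.

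A pseudocount of 0.1 gave 8 genes in U937, 443 in Jurkat and an overlap of 41 genes between stimulations; a pseudocount of 5 gave 47 in THP-1, 13 in U937 and 14 for the LPS difference. Without a filter 61 genes were called in THP-1, 20 in U937 and 26 for the LPS difference; with a minimum of 5 TPM, which tests fewer genes, 11 in THP-1 and 1 for the LPS difference. A minimum change of 1 left 3375 genes in untreated U937. Median-of-ratios scaling gave 13 in U937, and quantile normalization 14 in U937 and 4 for the LPS difference. Without trend the counts were 12 in THP-1 and 3 for the LPS difference. Own-line fits, which keep 2 residual degrees of freedom, called 0 genes in THP-1 and 0 in U937 by limma (1027 and 458 with an unadjusted p under 0.05), 368 in Jurkat and 12 in BJAB. Fits of the controls alone gave 8448, 8702, 8917 and 8945 for untreated THP-1, U937, Jurkat and BJAB.

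With the replicate number as a block (replicate block), 8 genes were called in THP-1, 4 in U937, 477 in Jurkat, 541 in BJAB and 2 for the LPS difference, and 30 lists. Libraries of a line with the same number were not shown to pair: their residuals correlated at 0.012 in THP-1, -0.042 in U937, 0.017 in Jurkat and 0.142 in BJAB.

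With 2 libraries left out, 37 genes were called in THP-1, 1942 in Jurkat and 4 for the LPS difference, 8010, 8281, 8474 and 8559 in the untreated lines in the order above, and 265 in the overlap. Of the 921 genes called in BJAB, 696 were kept among 1328. voom gave 8 in THP-1 and 0 for the LPS difference (770 with an unadjusted p under 0.05). Array weights gave 56 in THP-1, 2 in U937, 1860 in Jurkat, 214 in BJAB, 1 for the LPS difference, and 8791, 9005, 8896 and 8709 in the untreated lines. With an estimated correlation 9 of the 29 list calls held, and fry called 18, with 15 of the 29 among them. Outside the 29, fry called germinal centre genes (adjusted p = 0.0143) and T lineage markers (0.014) downward in BJAB. It also called T lineage markers downward in Jurkat (0.0207). Over the genes called in either line the LPS responses correlated at 0.671, by the choice of genes.

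Leaving out each library in turn gave 14 (without the first control) to 70 genes (without the first LPS library) in THP-1 and 3 to 5001 in U937 (without its first and second LPS library, 8 without its second control). It gave 431 (first control) to 480 in Jurkat, with 448 without the second control and 461 without the second stimulated library. In BJAB it gave 320 (second control) to 4179 (second stimulated library), with 408 without the first control and 447 without the first stimulated library. For the LPS difference it gave 3 (first THP-1 control, first U937 LPS library) to 2567 (second U937 LPS library), with 17 without either THP-1 LPS library. For the untreated lines it gave 3242 to 4572 in THP-1, 3278 to 4734 in U937 and 3633 to 5015 in Jurkat, the lowest always without the first control of the line; the second control gave 3345 and 3421 in THP-1 and U937. The lone library of a group is assumed to vary like the other groups. At 4125221 to 8431295 reads, a gene listed at 0 is not shown to be silent.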

Other observations

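The gene families below were chosen after their values were seen, as were the tests of the markers of other lineages in Jurkat.

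Relatives of the leading BJAB genes did not all move with them. Of 9 tested SLAM family receptors, which mediate contacts between lymphocytes, LY9 and SLAMF7 rose and SLAMF6 (34.0 and 27.7 TPM in controls, 0.467 and 7.46 TPM after stimulation; log2 change -3.17 ± 0.58, n = 2 per group, limma adjusted p = 0.00813) and CD84 (-1.70, adjusted p = 0.0128) fell. With the first stimulated libraries of U937 and BJAB left out, SLAMF6 changed by -1.91. These 4 calls held under median-of-ratios scaling, where CD244 rose too, and quantile normalization, where CD244 and SLAMF1 rose too. Of 14 RGS genes, RGS1, RGS2 and RGS13 rose and RGS3 fell (-1.69, adjusted p = 0.0018). The call of RGS3 was lost after removal of GC and length trends (-0.89, adjusted p = 0.119). RGS19 (199 and 220, then 19.1 and 125 TPM; adjusted p = 0.074) passed under quantile normalization (0.0416) and with those libraries left out (0.00944). Of 13 Toll-like receptors and partners, CD180, a TLR4-related receptor of B cells, rose from 99.0 and 102 to 364 and 562 TPM (2.16 ± 0.45, adjusted p = 0.0171). TLR10 (197 and 140, then 22.1 and 39.8 TPM; -2.45 ± 0.26, adjusted p = 0.000194), TLR4 (-2.07), TLR6 (-1.39, or -0.90 with the same libraries left out) and LY86 (-1.09) fell. The calls of TLR10, TLR4 and CD180 held under both scalings; LY86 missed the threshold under both (adjusted p = 0.217 and 0.0911) and TLR6 under quantile normalization (0.0655) and with the first stimulated libraries of U937 and BJAB left out (0.104). TLR9 (91.1 and 116, then 3.51 and 41.0 TPM; adjusted p = 0.0602) passed under both scalings (0.0468 and 0.0317) and not with those libraries left out (0.0623).

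In Jurkat, 7 genes of antigen receptor recombination and of the pre-antigen receptors were tested. RAG1, RAG2 and VPREB1 fell, under both scalings as well. The surrogate light chain IGLL1 was at 301 and 298 TPM in controls and 111 and 126 TPM after stimulation (limma adjusted p = 0.0737), and DNTT had an adjusted p of 0.236. IGLL1 passed under quantile normalization (0.0178) and after removal of GC and length trends (0.0184), but not under median-of-ratios scaling (0.164). With the first stimulated libraries of U937 and BJAB left out, 5 of the 7 fell.

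Untreated Jurkat libraries listed CD79A, a B cell receptor chain, at 135 and 161 TPM and CTSG, a myeloid granule protease, at 485 and 490 TPM, which is 9.14% of the BJAB level and 10.4% of the U937 level. BJAB material mixed into the libraries may be set aside as the source of CD79A: 11 other B lineage markers above 100 TPM in BJAB stood at a median of 0.0604% of their BJAB level in Jurkat, with BLK (22.1%) and POU2AF1 (3.99%) as exceptions. U937 material is argued against in the same way for CTSG, with a median of 0.115% over 7 other monocytic markers and CFD (41.2%) as the exception. Reads of its relative GZMB do not account for CTSG either, since CTSG changed by -0.68 (281 and 326 TPM after stimulation, adjusted p = 0.486) where GZMB rose by 6.95. Expression of both genes by the Jurkat cells themselves remains a hypothesis, found and tested on the same data.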
